A study of Mus musculus with 6 samples.

How the data were processed

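Total RNA was extracted with Trizol from subcutaneous white fat and transcribed into biotin-labelled complementary RNA for an Affymetrix mouse array, per the labels' protocols. The deposited values are probe set intensity values on a linear scale, made by the authors with RMA (background correction, quantile normalization and summary of the probes of each probe set), per the submitters' processing notes. The version of RMA and the annotation behind it are not given in the sources used here. The linear scale was read from the values, which ran from 5.4 to 25730.1, since the notes do not state it. RMA makes the distributions of all arrays alike, so a change of total RNA per cell cannot appear in these values. It also compresses low values, and lower quartiles lay between 29.9 and 31.7 on each array. Medians per array ranged from 123.15 to 130.35. The array's control probe sets for the mouse Gapdh and actin transcripts gave log2 ratios of the 3 prime over the 5 prime probe set. These ran from 0.11 to 0.23 for Gapdh and from 0.83 to 1.11 for actin.

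The 6 arrays were assigned to control (n = 3) and YY1bKO (n = 3) by the genotype in the labels. No pair of arrays was a duplicate, since Spearman correlations across genes ran from 0.946 to 0.993 and at most 212 of 22690 probe sets held identical values in any pair. Genes were named from the platform's annotation table. Of the 22690 probe sets, 20393 carried 1 gene symbol, 691 carried several and 1606 had no gene in that table, 64 of them Affymetrix controls. Symbols of 20364 probe sets were matched by gene identifier to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names and neighbouring genes. Probe sets with several genes or none were left out of tests of named genes. A gene with several probe sets, as 4958 of the 12394 genes had, was represented by the one with the highest mean over all 6 arrays, and disagreement in sign between probe sets is given where such a gene is named. There was no filter on dim probe sets.

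Values were transformed as log2(value + 1), with a pseudocount of 1, and tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which used 6.11 total degrees of freedom. P-values are 2-sided and were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Of Yy1 and Ucp1, exact 2-sided permutation tests were also run. Comparison, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule took Yy1 and Ucp1, then the 10 genes with the largest rise and the 10 with the largest fall past the threshold whose groups did not overlap, filled where fewer passed by the smallest unadjusted p in that direction, leaving out clone and predicted names. It further took up to 4 members with the smallest p of each gene list described, Cidea, Dio2, Ppargc1a and Prdm16 of the thermogenic list, Fgf21, Gdf15, Angptl6, Nmb and Nucb2 of the secreted factors, and all sex-linked genes and Ucp1 neighbours.

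The 36 gene lists, each with at least 3 measured members (6 to 72), covered thermogenic, mitochondrial and lipid metabolism, stress and hormone signalling, secreted factors, and markers of the cell types and tissues that inguinal fat could hold. They were tested with camera at a preset correlation of 0.01 and adjusted over the 36 lists, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, while fry tests whether its members move on balance in one direction. With an estimated correlation 0 of the 36 lists passed, and 1 had an unadjusted p under 0.05. The step for single genes was tested on simulated data with the means of these 12394 genes, in 20 simulations of 200 changed genes. It recovered 63.6% of genes changed by a log2 value of 1, 87.8% of those changed by 2 and 96.7% of those changed by 4, with 5.28% of its calls false. In 20 simulations that raised the fatty acid oxidation list by 0.5 in independent genes, camera recovered it in 20, with 3 calls of other lists in all. Camera with an estimated correlation recovered it in 16 and fry in 20. Genes varied independently in both kinds of simulation. In the data the estimated correlation of the 14 lists past the camera threshold ran from 0.12 (thermogenic) to 0.94 (ribosomal protein). The simulated rates therefore do not carry over to lists of correlated genes. Rates for single genes depend on how many genes change, since the Benjamini-Hochberg threshold is easier to meet when many do. In the data 4 genes passed, and Acaa2, with a log2 difference of 1.00 ± 0.09 (SE), did not (limma adjusted p = 0.0539). The rates for single genes therefore do not carry over to these data either.

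Alternatives tried were quantile normalization of the log2 values, subtraction of array medians, filters on dim probe sets at the 25th and 50th percentile, the mean of all probe sets of a gene, eBayes with an intensity trend or robust, array weights, the replicate number as a block, leaving out each array in turn, every probe set tested by itself, other thresholds, and other list tests. Chosen after seeing the data were a fit with no pseudocount and a fit without control replicate 2 and YY1bKO replicate 1. No batch or scan information was used here. Other fat depots of the study were not analysed here.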

Results

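Gene expression was measured in subcutaneous white fat of mice, labelled IWAT and read here as inguinal, by hybridising biotin-labelled RNA to Affymetrix arrays. Control mice carried floxed alleles of Yy1, which encodes the zinc finger transcription factor YY1, and the other group (YY1bKO) carried the same alleles together with a Cre recombinase driven by Ucp1 regulatory sequences, which act mainly in thermogenic adipocytes. Mice of both groups were 8 weeks old, of a mixed genetic background, and had received a high fat diet for 2 weeks. There were 3 arrays per group, and their number limits the precision of every value. Nothing in the labels states that the replicates came from separate animals, so the p-values measure the spread between these samples. The deposited intensities had medians from 123.15 to 130.35 per array, and 12394 genes were tested. Fold changes are on the log2(intensity + 1) scale, which understates the change of low genes. The labels name no group with Cre and without floxed Yy1, so effects of Cre or of its transgene are not separated from loss of YY1 in any change given here. The comparison asks how inguinal fat differs between floxed mice with and without that transgene, under a series title that concerns secreted proteins, energy expenditure and diet-induced obesity.

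Yy1, the targeted gene, was measured in every sample first. Its log2 values were 10.33, 10.52 and 10.62 in the control arrays and 10.13, 10.41 and 10.20 in the YY1bKO arrays. The log2 difference was -0.24 ± 0.12 (SE, n = 3 per group; 95% confidence interval -0.54 to 0.06), with a limma adjusted p of 0.574. An exact 2-sided permutation test of the same values gave p = 0.2, where the smallest p that 3 against 3 arrays allow is 0.1. The 4 Yy1 probe sets gave log2 differences of -0.24, -0.19, -0.07 and -0.11, none past the threshold. Whether any of them lies in the deleted part of the gene is not given in the sources used here, and a probe set outside it checks nothing. The deletion is also restricted to Ucp1-expressing cells, so whole inguinal fat tests the labels only in part. Few cells of this depot may express Ucp1, whose control intensity was 47.9 ± 5.05 (SD, n = 3). Changes given here therefore cannot be assigned to loss of YY1 within inguinal fat rather than in another depot.

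Inguinal fat of YY1bKO mice had far higher transcript levels of Ucp1, the uncoupling protein of brown and beige adipocytes, than that of control mice. Fabp3, a fatty acid binding protein abundant in oxidative tissues, and Slc27a2, a very long chain acyl-CoA synthetase, rose with it, as did Chrna2, a subunit of the nicotinic acetylcholine receptor. Ucp1 (probe set 1418197_at) rose 38.2-fold, from a log2 value of 5.61 ± 0.15 to 10.86 ± 0.18 (SD, n = 3 each), with a log2 difference of 5.25 ± 0.14 (SE) and an adjusted p of 1.91e-04. On the linear scale its intensity went from 47.9 ± 5.05 to 1867 ± 232 (SD), and the exact permutation test gave p = 0.1, the smallest it can give. Fabp3 (1416023_at) rose from 5.45 ± 0.57 to 11.24 ± 0.25, with a log2 difference of 5.79 ± 0.30 and an adjusted p of 0.00638. Slc27a2 (1416316_at) rose from 4.27 ± 0.45 to 7.94 ± 0.06, with an adjusted p of 0.0114. Chrna2 (1425409_at) rose from 4.62 ± 0.04 to 5.79 ± 0.11, with an adjusted p of 0.0475. The control values of Slc27a2 and Chrna2 lay below the lower quartile of intensities of every array (29.9 to 31.7), and 2 of the 3 of Fabp3 lay close above it (5.14 and 5.10 on the log2 scale), so the size of these rises is not exact. These 4 genes were the only ones of the 12394 past an adjusted p of 0.05 by limma, all higher in YY1bKO in 3 of 3 arrays.

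The genes next in order did not pass the threshold. Acsm3, a medium chain acyl-CoA synthetase, was 2.49-fold higher (adjusted p = 0.0503), and Fbxo21, a ubiquitin ligase subunit, had a log2 difference of 0.96 (0.0503). Acaa2, the thiolase of mitochondrial fatty acid oxidation, Sfxn1, a mitochondrial serine carrier, Retsat, retinol saturase, and Gsta3, a glutathione transferase, had log2 differences of 1.00, 0.87, 1.32 and 1.49, each with an adjusted p of 0.0539. No gene fell at an adjusted p under 0.05 by limma, while 247 were lower and 1047 higher at an unadjusted p under 0.05, where chance gives 5% of genes and the data gave 10.4%. The lower genes with the smallest p were Tnk2, a non-receptor tyrosine kinase (-0.89), Ckap4 (-0.63), Dtl, a ubiquitin ligase receptor of the replicating cell (-0.65), Myo1e (-0.50) and Cd44, the hyaluronan receptor (-0.94). Cmip (-0.48), Lrrfip1 (-0.94, with 3 probe sets from -0.94 to -0.22), Phtf2 (-0.48), Tlr6 (from 5.77 to 4.73) and Rcc1 (-0.39) followed. The YY1bKO mean of Tlr6, not its control mean, lay below the lower quartile of every array, so its fall is not exact. The limma adjusted p of these 10 lower genes lay between 0.138 and 0.21. The 2 groups did not overlap in 2046 genes, 16.5% of those tested, where chance gives 10%. Single arrays moved the counts at an unadjusted p under 0.05 by limma. They were 1631 higher and 572 lower without control replicate 1, and 564 and 96 without YY1bKO replicate 3. Without YY1bKO replicate 1, 2 or 3, in turn, 1 gene passed, Ucp1, and the same count held without control replicate 2 and YY1bKO replicate 1 together, an alternative chosen after seeing the data. In those 3 fits the log2 differences of Fabp3 were 5.84, 5.65 and 5.88 and those of Slc27a2 3.64, 3.68 and 3.70, and those of Chrna2 1.15, 1.24 and 1.14. Chrna2 also missed the threshold without control replicate 1, 2 or 3 (1.18, 1.15 and 1.19), and it passed in 5 of the 16 alternatives that hold it.

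Genes that mark brown and beige adipocytes were higher in YY1bKO as a group, led by Ucp1, Fabp3 and Slc27a2. Elovl3, a fatty acid elongase induced by cold in brown fat, was 4.44-fold higher, from 5.73 ± 0.14 to 7.88 ± 0.41 (SD, n = 3 each; adjusted p = 0.0539 over all genes). Ppargc1a, the coactivator of mitochondrial biogenesis, was 1.89-fold higher (0.326), with 5 probe sets from 0.50 to 1.17. Dio2, the deiodinase that activates thyroid hormone, showed a log2 difference of 0.07 (0.868), from a mean of 5.22 to 5.29, with 3 probe sets from -0.13 to 0.07. No probe set named Prdm16 alone in the annotation table, so Prdm16 was not tested. Of the 26 measured members of the list, 3 rose when adjusted over all genes and 8 when adjusted over the list alone. Besides the 5 genes above, these 8 held Cox7a1 (2.39) and Cox8b (1.57), muscle and brown fat forms of cytochrome oxidase subunits, and Letmd1 (0.60), named here after their values were seen. The list's median log2 difference was 0.36 and its mean 1.06, with a camera adjusted p of 4.52e-09. That call was lost with an estimated correlation (adjusted p = 0.679 with an estimated correlation) and held by fry (adjusted p = 0.0163). The median was 0.60 without the probe sets below the 25th percentile of brightness and 0.76 without those below the 50th. Cidea, a lipid droplet protein of brown adipocytes, had values of 8.86, 11.01 and 8.84 in the controls and a mean of 10.80 ± 0.10 (SD, n = 3) in YY1bKO. Its log2 difference of 1.23 ± 0.59 (SE) did not pass (0.555), and without control replicate 2 it was 1.95 and passed (adjusted p = 0.0267, in a range from 0.0267 to 0.979 over all alternatives). Control replicate 2 also had the highest skin and mammary epithelium list means (1.53 and 1.67). Whether other tissue in that sample gave its high Cidea value was not tested. The neighbours of Ucp1 on its chromosome that were measured, Il15 (0.36, adjusted p = 0.599) and Zfp330 (0.02, 0.977), did not pass. Elmod2, Tbc1d9, Rnf150 and Inpp4b, the other neighbours listed, were not among the genes tested, so a local or transgene effect at Ucp1 is not addressed.

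**Figure D1:**
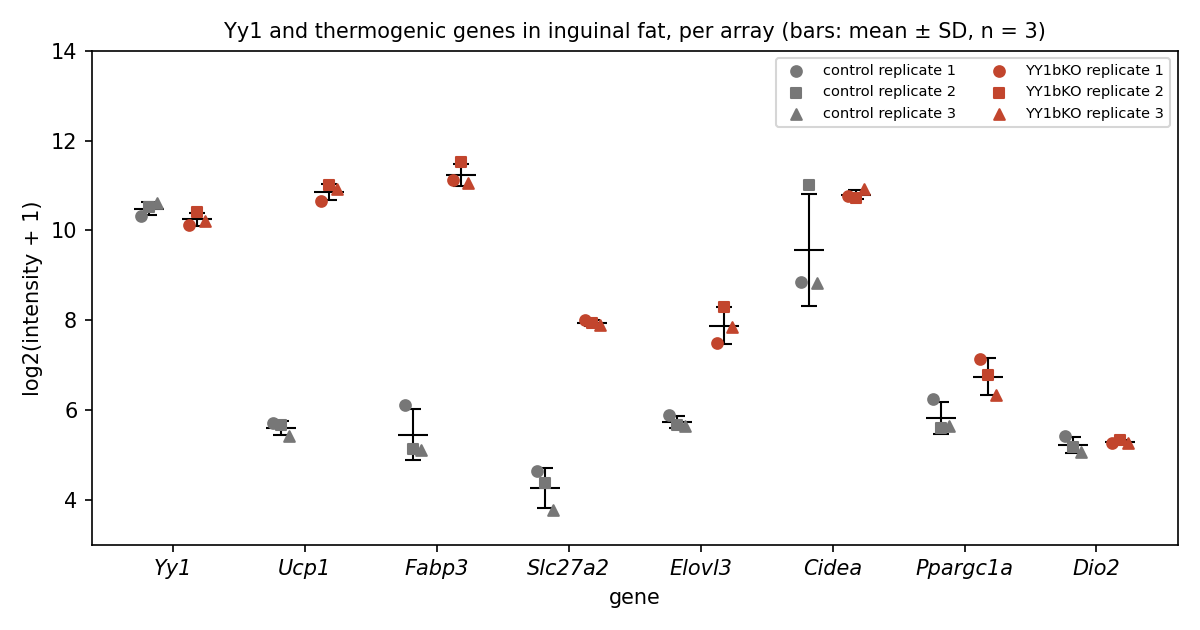
Log2(intensity + 1) of Yy1 and 7 thermogenic genes in each of the 6 arrays, with controls in grey and YY1bKO in red, and bars for the mean ± SD of 3 arrays. Ucp1 lies near 5.61 in the controls and 10.86 in YY1bKO, whereas Cidea in control replicate 2 (11.01) lies with the YY1bKO arrays. That control array also had the highest skin and mammary epithelium list means.

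Genes of mitochondrial fuel use were higher together in YY1bKO fat. Mitochondrial fatty acid oxidation genes showed the largest shift of these, followed by the tricarboxylic acid cycle and by the nuclear-encoded subunits of the respiratory chain and ATP synthase. In each of these 3 lists and in the thermogenic list, every YY1bKO array had a higher list mean than every control array. The groups' arrays did not overlap in 5 of the 36 lists in all, where chance gives 10% for any 1 list. Of 19 fatty acid oxidation genes, 18 were higher and 15 rose when adjusted over the list alone, with a median log2 difference of 0.61. Examples were Acaa2 (1.00), Eci1, an enoyl-CoA isomerase (1.09), Acadvl, the very long chain acyl-CoA dehydrogenase (0.87), and Acot2, a mitochondrial thioesterase (1.16). Of 19 tricarboxylic acid cycle genes, all were higher and 11 rose when adjusted over the list alone, among them Ogdh (0.71), Sdhb (0.52), Idh3g (0.53) and Idh3b (0.41). The median of that list was 0.36. Of 72 oxidative phosphorylation genes, 70 were higher, but only Uqcrq (0.77) and Sdhb (0.52) rose when adjusted over the list alone, and the 4 probe sets of Uqcrq ranged from -0.12 to 0.77. The median of that list was 0.27. Adjusted over all genes, 0 members of these 3 lists passed by limma, while 15 of fatty acid oxidation, 12 of the tricarboxylic acid cycle and 40 of oxidative phosphorylation were higher at an unadjusted p under 0.05. The last 2 lists share the succinate dehydrogenase subunits. The camera adjusted p was 1.41e-13 for fatty acid oxidation, 2.75e-11 for the tricarboxylic acid cycle and 8.58e-20 for oxidative phosphorylation. All 3 calls were lost with an estimated correlation (adjusted p = 0.679 with an estimated correlation) and by fry (adjusted p = 0.0737). White adipocyte genes, described with the lipid-handling lists, had a median of 0.28 in the same arrays. YY1bKO replicate 1, with the highest skeletal muscle (1.90) and lowest B cell list mean (-2.15), had the highest means of fatty acid oxidation, the tricarboxylic acid cycle and oxidative phosphorylation (0.36, 0.25 and 0.18), and control replicate 3, with the highest B cell mean (2.02), the lowest (-0.51, -0.34 and -0.23). The medians were 0.57, 0.33 and 0.25 without that YY1bKO array and 0.52, 0.32 and 0.22 without that control array, all past the camera threshold.

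**Figure D2:**
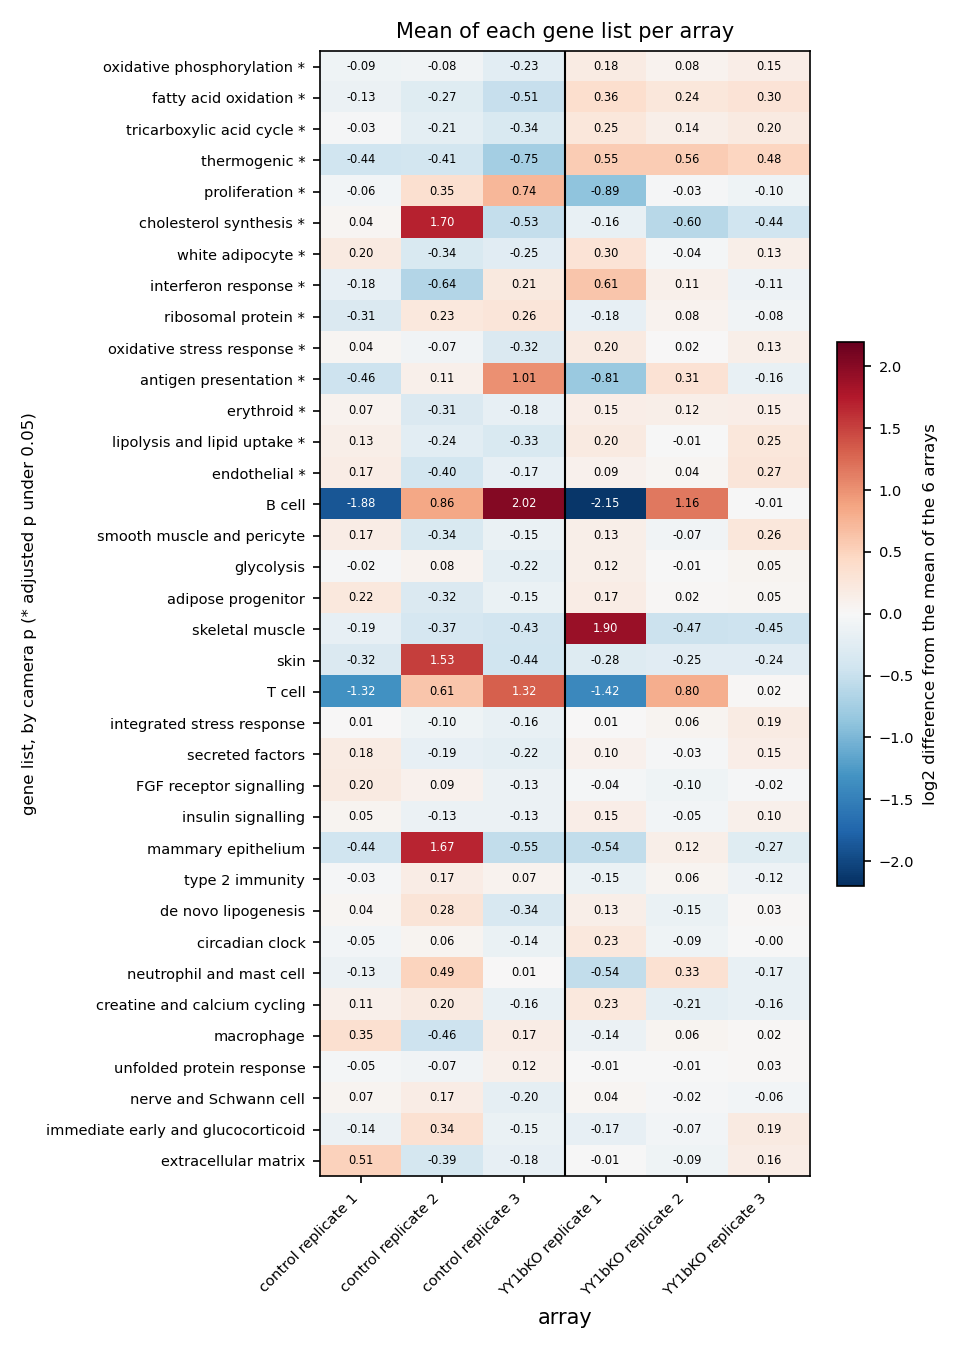
Mean over the members of each of the 36 gene lists (vertical axis) in each of the 6 arrays (horizontal axis), as the log2 difference from the mean of the 6 arrays, with red for higher, blue for lower, and an asterisk on the 14 lists past the camera threshold. The fatty acid oxidation list is at most -0.13 in the controls and at least 0.24 in YY1bKO, whereas the cholesterol synthesis list stands at 1.70 in control replicate 2 and at 0.04 or below in the other arrays.

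Genes of the lipid store and of adipocyte identity were also higher in YY1bKO as groups. In the white adipocyte list 12 of 14 genes were higher, and Nnat, neuronatin (0.95), and Agt, angiotensinogen (0.83), rose when adjusted over the list alone. In the list of lipolysis and lipid uptake 8 of 11 were higher, and Pnpla2 (1.00) and Lipe (0.83), the lipases that open triglyceride breakdown, rose when adjusted over the list alone. Among oxidative stress response genes 13 of 17 were higher, and Gpx3, the secreted glutathione peroxidase (1.20), Gstm1 (0.69) and Sod1 (0.58) rose when adjusted over the list alone, although the 2 probe sets of Sod1 gave -0.06 and 0.58. Erythroid genes were higher in 6 of 6, with Fech (0.43) and Hbb-b2 (0.30) past the threshold when adjusted over the list alone, and the groups' arrays did not overlap in that list's mean. Interferon response genes were higher in 17 of 19 and endothelial genes in 13 of 15, with 0 members past the threshold by limma in either count, 1 and 3 higher and 0 and 1 lower (Prox1, -0.24, near the floor) at an unadjusted p under 0.05, and examples in Irf7 (0.68), Oasl2 (0.96), Robo4 (0.62) and Lyve1 (0.56). No member of these 6 lists passed over all genes by limma, and at an unadjusted p under 0.05 3 white adipocyte, 3 lipolysis, 4 oxidative stress and 3 erythroid genes were higher. Camera adjusted p values were 0.0089 (white adipocyte, median 0.28), 0.0231 (lipolysis, 0.26), 0.0183 (oxidative stress, 0.27), 0.0231 (erythroid, 0.28), 0.0101 (interferon, 0.35) and 0.0261 (endothelial, 0.26), and all became adjusted p = 0.679 with an estimated correlation and at least 0.215 by fry. Calls were also lost without the probe sets below the 50th percentile (white adipocyte, 0.112; lipolysis, 0.102; erythroid, 0.0564) or the 25th (lipolysis, 0.05004), with the mean of all probe sets (lipolysis, erythroid and endothelial, each 0.0528), on ranks (lipolysis, 0.0532, and oxidative stress, 0.0540) and with array weights (interferon, 0.0925). The white adipocyte list means were 0.20, -0.34 and -0.25 in the controls and 0.30, -0.04 and 0.13 in YY1bKO, beside B cell list means of -1.88, 0.86 and 2.02 and of -2.15, 1.16 and -0.01. Control replicate 2, which had the highest skin and mammary list means (1.53 and 1.67), had the lowest of white adipocyte (-0.34), endothelial (-0.40) and erythroid genes (-0.31). Without control replicate 2 the white adipocyte, lipolysis, erythroid, interferon and endothelial lists no longer passed (medians 0.12, 0.15, 0.20, 0.17 and 0.13), and without control replicate 3 the same held for white adipocyte, lipolysis, oxidative stress, erythroid and endothelial genes (0.20, 0.18, 0.03, 0.26 and 0.23). The interferon call also ended without control replicate 1 (0.38) or YY1bKO replicate 1 (0.24), which had the highest mean of that list (0.61), and the endothelial call without YY1bKO replicate 3 (0.20), while without control replicate 1 the white adipocyte and endothelial medians were 0.44 and 0.49, without control replicate 3 the interferon median was 0.60 and without YY1bKO replicate 1 the white adipocyte median was 0.13.

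Cell cycle genes were lower in YY1bKO fat by camera, and so were genes of cholesterol synthesis, antigen presentation and the cytosolic ribosome. In the mean of each of these lists the arrays of the 2 groups overlapped. Of 19 proliferation genes 18 were lower, with a median of -0.70 and a camera adjusted p of 1.76e-08, a call lost with an estimated correlation (adjusted p = 0.679 with an estimated correlation). Cdk1 (-0.67), Ube2c (-0.72), Birc5 (from 6.80 to 5.79) and Aurkb (from 5.43 to 4.96, near that quartile), all acting in mitosis, had the smallest p of that list. Of 15 cholesterol synthesis genes 14 were lower, with a median of -0.80 and an adjusted p of 0.00145, a call lost in the same way (0.679) and without control replicate 2, which held a list mean of 1.70 (median then -0.12). They included Hmgcs1 (-1.19), the synthase upstream of the rate-limiting step, Srebf2 (-0.71, with probe sets at -0.71 and -0.20), the main transcription factor of the pathway, and Nsdhl (-0.72), and the exception was Fdft1 (0.43), whose 4 probe sets ranged from -0.14 to 0.48. All 8 class II antigen presentation genes were lower, with a median of -0.41 and an adjusted p of 0.0190 (0.679 with an estimated correlation), among them Ctss (-0.51), H2-Eb1 (-0.39) and Cd74 (-0.40). Of 32 ribosomal protein genes 30 were lower, with a median of -0.09 and an adjusted p of 0.0111 (0.679 with an estimated correlation). No member of these 4 lists fell, whether adjusted over all genes or adjusted over the list alone, by limma, and 3 proliferation genes, 1 cholesterol synthesis gene and 0 of the other 2 lists were lower at an unadjusted p under 0.05. By fry the adjusted p of the 4 lists was at least 0.382. The proliferation list means were -0.06, 0.35 and 0.74 in the controls and -0.89, -0.03 and -0.10 in YY1bKO, where the B cell list means given above were also lowest in replicate 1. Antigen presentation means were -0.46, 0.11 and 1.01 in the controls and -0.81, 0.31 and -0.16 in YY1bKO, which orders the arrays as the B cell means do. Ribosomal means were -0.31, 0.23 and 0.26 in the controls and -0.18, 0.08 and -0.08 in YY1bKO. Lymph node content was not tested as a source for these last lists. Without control replicate 2 the ribosomal list did not pass (-0.02). Without control replicate 3 the antigen presentation (-0.08) and ribosomal lists (-0.0035) did not pass and the cholesterol median was -1.33, and without YY1bKO replicate 1 the antigen presentation (-0.21) and ribosomal lists (-0.05) did not pass and the proliferation median was -0.42. The ribosomal median was -0.27 without control replicate 1 and -0.18 without YY1bKO replicate 2, where the antigen presentation median was -0.63.

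Secreted proteins tied to energy expenditure, the subject of the series title, included members that were higher in YY1bKO fat. Nrg4, a neuregulin released by brown adipocytes (0.97), Nmb, neuromedin B (0.68), and Nampt (0.64) rose when adjusted over the list alone, 3 of 18 measured, and 0 of 18 passed by limma over all genes, where their adjusted p was 0.139, 0.173 and 0.274 and 5 were higher at an unadjusted p under 0.05. Angptl6 had a log2 difference of 0.39 (adjusted p = 0.343), Fgf21 of 0.12 (0.845) and Nucb2, the precursor of nesfatin, of -0.05 (0.917). No probe set named Gdf15 alone in the annotation table, so Gdf15 was not tested. Whether a probe set with several genes or none reads it was not examined. The list as a whole did not pass (median 0.05, camera adjusted p = 0.153), except without control replicate 1 (0.22, 0.0172). Its median ran from -0.0059, with an array left out, to 0.49 over all alternatives. Among ATF4 targets of the integrated stress response, Trib3 (0.94), Asns (0.86) and Ddit3 (0.44) rose when adjusted over the list alone, 3 of 19. The list did not pass (median 0.08, from 0.08 to 0.22 with each array left out, camera adjusted p = 0.118). Single members also rose when adjusted over the list alone in the insulin signalling list (Pck1, 0.82, with probe sets at 0.01 and 0.82; list adjusted p = 0.187), de novo lipogenesis (Thrsp, 0.85; 0.258), glycolysis (Slc2a4, the insulin-regulated glucose transporter, 0.88; 0.112) and nerve and Schwann cell genes (Mbp, 0.93, with 8 probe sets from -0.32 to 1.00; 0.692). No member passed, over all genes or adjusted over the list alone, in FGF receptor signalling (0.168), circadian clock (0.415), creatine and calcium cycling (0.542), macrophage (0.660), type 2 immunity (0.238), neutrophil and mast cell (0.498), adipose progenitor (0.112), smooth muscle and pericyte (0.0777), unfolded protein response (0.673), immediate early and glucocorticoid (0.724) and extracellular matrix genes (0.991), and the camera adjusted p in brackets did not pass either. By limma, 0 to 4 members of each of these 11 lists had an unadjusted p under 0.05. In unfolded protein response, immediate early and glucocorticoid, and extracellular matrix genes and in nerve and Schwann cell genes, the median, the mean and the direction of the test differed in sign. Of the 11 lists, 5 passed with some array left out: without control replicate 1 extracellular matrix (median 0.30), adipose progenitor (0.36) and smooth muscle and pericyte genes (0.41), the last also without YY1bKO replicate 2 (0.27), without control replicate 2 macrophage genes (-0.30), and without control replicate 3 FGF receptor signalling (-0.17). Adipose progenitor genes also passed with array weights (0.20) and smooth muscle and pericyte genes with array weights (0.33) or the replicate block (0.22). Without control replicate 2 and YY1bKO replicate 1 together, chosen after seeing the data, macrophage (-0.29) and glycolysis genes (0.11) passed.

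Markers of tissues that border inguinal fat varied between single arrays, and 0 of their members passed by limma, with at most 1 per list at an unadjusted p under 0.05. Skeletal muscle genes had a list mean of 1.90 in YY1bKO replicate 1 and at most -0.19 in the other arrays, and their median difference of 0.67 did not pass (camera adjusted p = 0.112). Without YY1bKO replicate 1 that median was -0.25 and the list passed as lower. Acta1, skeletal actin (2.08), did not follow the list. Its log2 values were 8.29, 7.51 and 8.22 in the controls and 10.62, 9.04 and 10.62 in YY1bKO. Skin genes (median -0.08, adjusted p = 0.117) and mammary epithelium genes (-0.11, 0.187) had list means of 1.53 and 1.67 in control replicate 2, and at most -0.24 and 0.12 in the other arrays. Their medians were 0.05 and 0.14 without that array and -0.55 and -1.02 without the probe sets below the 25th percentile, and that of mammary genes was -0.54 without control replicate 1, none past the threshold. B cell genes (-0.67, 0.0681) and T cell genes (-0.42, 0.117) had their lowest list means in control replicate 1 and YY1bKO replicate 1 (T cell -1.32 and -1.42) and their highest in control replicate 3 (1.32). The B cell list passed as lower without control replicate 1 (-1.85), YY1bKO replicate 2 (-1.34) or YY1bKO replicate 3 (-0.80), and the T cell list without control replicate 1 (-1.22) or YY1bKO replicate 2 (-1.11). Without control replicate 3 or YY1bKO replicate 1 neither passed, and the medians were 0.31 and 0.24 for B cell and 0.27 and 0.22 for T cell genes. Array weights (-1.01 and -0.76) and the replicate block (-0.67 and -0.42) gave both lists as lower, and ranks the B cell list. Further calls were those of the skin and mammary lists without control replicate 3 (-0.20 and -0.49), and of the muscle list as higher without YY1bKO replicate 2 (1.05) or 3 (0.98) or with the replicate block (0.67). In a principal component analysis the first component, 50.7% of the variance, placed control replicate 2 at 56.8 and the other arrays between -27.5 and 9.84. The Y chromosome genes Kdm5d, Uty and Eif2s3y (8.51 to 9.82) were expressed in all 6 arrays, Usp9y lay near the floor (3.31 to 3.61), and Xist, which silences the inactive X chromosome, lay between 5.30 and 5.81. Kdm5d (0.20, with 3 probe sets from -0.18 to 0.20), Eif2s3y (-0.30), Uty (0.17), Usp9y (-0.10) and Xist (-0.08, with 3 probe sets from -0.11 to 0.07) did not pass.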

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

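Outside the genes tested by name, 2 probe sets that name several genes or none rose in YY1bKO when every probe set was tested by itself with limma. Probe set 1418328_at, whose annotation names several genes, rose by 2.67 ± 0.16 (SE) on the log2 scale, from 6.80 ± 0.28 to 9.47 ± 0.14 (SD, n = 3 each), with an adjusted p of 0.0128. Probe set 1436934_s_at, with no gene in the annotation table, rose by 0.95 ± 0.08, from 10.69 ± 0.04 to 11.64 ± 0.05, with an adjusted p of 0.0452.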

How the results depend on the processing

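Chosen after seeing the data were the fits with no pseudocount and without control replicate 2 and YY1bKO replicate 1 together. The direction of Yy1 held in all 17 alternatives (-0.32 to -0.15), none past the threshold, and Ucp1 passed in all 17 (5.17 to 5.39, adjusted p from 7.38e-05 to 0.0173). Against 4 genes, 2 passed without the probe sets below the 50th percentile (a filter that also leaves out Slc27a2), 12 with robust eBayes, 9 with array weights, 11 with every probe set tested by itself, 15 at an adjusted p under 0.1, 1294 at an unadjusted p under 0.05, 1 without control replicate 2 and YY1bKO replicate 1, and 1 to 5 with each array left out in turn. With the replicate number as a block 1 gene and 18 lists passed. The numbers share no stated origin, and deviations of same-numbered arrays correlated at 0.61, 0.10 and 0.03, while control replicate 3 correlated best with YY1bKO replicate 2 (0.60), so not every array correlated best with its own number. Against 14 lists, 8 to 19 passed with each array left out (8 without control replicate 2), 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 by fry, and 11 to 18 in the others. The estimated correlation widens the spread camera assumes, and the cause of the other changes was not tested. Robust eBayes has no counterpart in camera and was not run for lists, and the filter at the 50th percentile left too few skin and mammary genes for a test. Turned in the direction of the test, among lists past the threshold before or after, were extracellular matrix without control replicate 1 (0.30, from -0.14 to 0.30 with each array left out; the test pointed down before), skeletal muscle without YY1bKO replicate 1 (-0.25, from -0.25 to 1.05) and, without control replicate 2 and YY1bKO replicate 1, skeletal muscle (-0.14), interferon response (-0.020), ribosomal protein (0.023) and mammary epithelium (0.24). Medians of lists past it in neither fit changed sign too, as without control replicate 3 in B cell (-0.67 to 0.31) and T cell genes (-0.42 to 0.27), and without control replicate 1 in macrophage genes (-0.09 to 0.21). Of the values of the 14 called lists under alternatives, 203 kept their call, 61 lost it and 2 turned. Of the 4 called genes' values 45 kept it and 21 lost it, and of the other named genes' values 2712 stayed on their side, 16 gained a call and 30 crossed 0 without one. Scaling moved the median log2 difference of all genes from 0.0046 to at most 0.0103, and the share of higher genes at an unadjusted p under 0.05 was 80.9%, 79.7% after quantile normalization, 70.6% without control replicate 2 and 68.0% without it and YY1bKO replicate 1. Signal near background limits low genes such as Dio2, and Slc27a2, Chrna2 and Fabp3 in the controls.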

Other observations

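Further lists of metabolic genes, 4 in all, were added after the main comparison was seen, and of these the mitochondrial ribosome and glutathione transferase lists were chosen only after their genes' values were seen, as were all tests of muscle, adipocyte share, the transgene, lymph node content, control replicate 2 and its candidate tissues. Genes of branched-chain amino acid breakdown were higher in YY1bKO fat in 16 of 17 cases, with a median log2 difference of 0.44. Hibch (0.82), Ivd (0.59) and Bckdk (0.59), the kinase that inhibits the branched-chain keto acid dehydrogenase, rose when adjusted over the list alone. Peroxisome genes were higher in 21 of 27 (median 0.23), with Ehhadh at 1.01 and Phyh at 0.67, and 0 rose when adjusted over the list alone by limma, with 5 at an unadjusted p under 0.05. The hypothesis that each of these lists is higher in YY1bKO gave a camera adjusted p, over the 4 lists, of 6.24e-08 (branched-chain amino acids) and 0.00211 (peroxisome). These became adjusted p = 0.150 and 0.357 with an estimated correlation, and by fry 0.0401 and 0.251. The arrays of the groups did not overlap in the list mean of branched-chain amino acid genes and did in that of peroxisome genes. Beyond the shift of the white adipocyte list they were higher by 0.16 ± 0.10 (SE; 0.11 to 0.25 with each array left out) and by -0.06 ± 0.24 (-0.20 to 0.18), so a larger share of adipocytes is not excluded for either. For the lists chosen after their values were seen a test decides nothing, so no list test is given. Counts of their genes at an unadjusted p are descriptions only. Subunits of the mitochondrial ribosome were higher in 67 of 74 (median 0.25), with Mrps15 at 0.74 and Mrps18a at 0.62, and beyond the white adipocyte shift by -0.02 ± 0.16 (-0.16 to 0.08 with each array left out). Glutathione transferases were higher in 13 of 18 (median 0.42), with Gsta3 at 1.49, Gstt2 at 0.76, Gstk1 at 0.71 and Gstm1 at 0.69, and beyond that shift by 0.12 ± 0.13 (-0.0051 to 0.22), and 3 of the 18 were in an earlier list. No member of these 4 lists passed over all genes by limma, where 8 genes of branched-chain amino acid breakdown, 5 of the peroxisome, 34 of the mitochondrial ribosome and 8 transferases had an unadjusted p under 0.05, and single genes are named after their values were seen.

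Ucp1, Fabp3 and Slc27a2 rose together, and technical sources for this were weighed against the genotype. Skeletal muscle in YY1bKO replicate 1 could bring Fabp3, but the lower of YY1bKO replicates 2 and 3 exceeded the highest control by 5.20, 4.96 and 3.24 on the log2 scale in the 3 genes. A larger share of adipocytes would raise white adipocyte genes by a like amount, and the median of that list was 0.28. Signal read from copies of Ucp1 on the Cre transgene concerns the Ucp1 probe set, and those of Fabp3 and Slc27a2 are annotated to other genes. The smaller of their log2 differences was 3.67, but these were known beforehand, so their size tests nothing about the transgene. For Ucp1 itself the array has 1 probe set, so transgene copies and the endogenous gene cannot be told apart. Indirect effects of Cre or of its transgene on all 3 genes stay open, as does the hypothesis that inguinal fat of these mice holds more, or more active, beige adipocytes, which mice with Cre and without floxed Yy1 and a count of UCP1-positive cells in sections would test. Whether loss of YY1 in another fat depot acts on inguinal fat was not tested.

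The mitochondrial lists were set against the share of adipocytes, with lymphoid and muscle content not tested for them, and the proliferation list against lymph node content. Fatty acid oxidation exceeded the shift of the white adipocyte list by 0.34 ± 0.14 (SE) on the log2 scale, 0.27 to 0.47 with each array left out and above 2 SE in 2 of these 6 cases, so a larger share of adipocytes stays open as its source. It stays open too for the tricarboxylic acid cycle (0.13 ± 0.12, from 0.04 without control replicate 1 to 0.22 without control replicate 2) and for oxidative phosphorylation (0.0051 ± 0.17, from -0.14 to 0.14 without the same arrays), since single arrays move these values. Proliferation genes may come in part from lymph node tissue. With the B cell list mean as a covariate their difference was -0.53 ± 0.13, against -0.68 ± 0.36 without it, and -0.62 to -0.39 with each array left out. The smallest of these was -0.39 ± 0.16 (SE), without control replicate 1. The difference kept its sign, but a model with a covariate on so few arrays leaves lymph node content open as a source. A difference in dividing cells between the genotypes remains a hypothesis, which staining of dividing cells in fat free of lymph node would test.

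Control replicate 2 stood apart from the other arrays, with 367 genes (2.96%) more than 1 log2 unit above all others, against 2 to 53 in any other array. Chosen after their values were seen, Cst6 (14.56), Perp (13.18), Sprr1a (12.89), Krt14 (12.45) and Olah (11.16) lay 7.20 to 8.92 above the next array. Of marker lists for candidate sources, 50% of interfollicular epidermis genes (6 of 12, with Krtdap at 11.98 and Dmkn at 12.79 but Krt1 at 4.22) and 20% of sebaceous gland genes (2 of 10, Krt79 at 12.82 and Elovl4 at 7.77, where 5 members are bright in fat) were that far above, so neither is settled, and 6 and 1 genes of these lists were in the first lists. Of hair follicle genes 6.25% (1 of 16, 4 in the first lists) and of mammary secretory epithelium genes 0% (0 of 10, 5 in the first lists) were that far above. These lists hold mostly hair keratins and milk genes. Their low values therefore do not exclude follicles that make no hair or mammary epithelium that makes no milk. Other glands of the region were not tested. The lower cholesterol synthesis list is consistent with this other tissue as its main source, since without control replicate 2 its median moved from -0.80 to -0.12, but without YY1bKO replicate 1 as well it was -0.28 and passed.

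The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4 genes past the threshold, and the highest of the others gave 2, so 1 of 10 splits, the real one, gave as many. It gave 14 gene lists and the highest other split 20, with 7 of 10 giving as many. The split that sets control replicate 1, YY1bKO replicate 1 and YY1bKO replicate 3 against the rest gave 2193 genes at an unadjusted p under 0.05 by limma, against 1294 in the real split, and 0 at an adjusted p under 0.05, which points to a structure of the samples, whose source was not tested, since the list means of B cell, ribosomal protein and white adipocyte genes all part the arrays this way. Of the 4 lists called lower, cholesterol synthesis and ribosomal protein had as small a camera p in 7 of 10 splits, the real one included. For antigen presentation it was 5 and for proliferation 2. In 5 of the 14 lists (thermogenic, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation and oxidative stress response) no other split gave as small a camera p. Since these 14 were picked by a small camera p in the real split, that split was favoured in advance. The count therefore decides nothing about them.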
